A study of Caenorhabditis elegans with 2 samples.

How the data were processed

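ChIP-seq peak lists of CEH-24 tagged with GFP were analysed for 2 biological replicates of whole late-embryo worms, which form 1 group. Per the file headers, the deposited lists are of 3 kinds. Each replicate has its own relaxed list of peaks and background, made as input for the irreproducible discovery rate (IDR) procedure, both replicates together have a pooled list of the same kind, and the series has a list of optimal peaks that passed the IDR threshold. Every list was deposited on the ce10 and the ce11 genome build. Coordinates below are on ce11, which is the assembly WBcel235 of the reference used here, and no coordinate was converted between builds. The highest peak end on each of the 6 nuclear chromosomes lay within the reference chromosome's length. The aligner, the peak caller and their versions and settings are not given in the sources used here.

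The signal value of a peak is the authors' own, as deposited, and was used to describe and rank peaks within 1 list. Its scale differs between lists, so values of the replicates were set beside each other only peak by peak and in correlations, with no difference tested. The −log10 q-value of a peak is likewise deposited by the authors. The column for the p-value holds no values. Per the file headers, each replicate and the pooled list were derived with the same control file, so the replicate lists share the chance values of that control. Read totals are not part of the lists, so the depth of either replicate is unknown and no interval could be based on reads. Intervals of shares are Wilson 95% intervals over peaks or genes, and all intervals given here cover counting error only. For a gene list with no bound gene, the limit given as "up to" is instead 3 divided by the number of genes. This approximation is too high for lists of few genes. Peaks are not independent replicates, so p-values describe these peak lists and not the spread between batches of worms.

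Peaks were annotated with Ensembl release 115 and the RefSeq genome sequence in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). A summit within 1000 bp of any of 29314 annotated protein-coding transcript starts counted as a promoter peak. The terms intergenic and intronic refer to protein-coding genes only, so a summit inside an RNA gene can count as intergenic. The background was the 29558 pooled peaks that overlapped no optimal peak. Most of these had a deposited q-value above 0.05. Shares were compared with 2-sided Fisher's exact tests, and odds ratios carry Woolf 95% intervals with 0.5 added to each cell. The addition raises odds ratios that rest on few bound genes, so their intervals can lie above 1 without a low Fisher p. A matched background held 10 background peaks per peak, from the same of 5 classes of GC content and the same class of distance to the nearest protein-coding start. Sequence was searched on both strands within 100 bp of the summit, a window of 201 bp. The NK-2 class site was TNAAGTG. All 2080 6-mers, each taken with its reverse complement, were tested for presence in the window with Benjamini-Hochberg adjustment and a threshold of 0.05. Fixed lists of genes, 21 in all, were tested for bound promoters against the 9969 protein-coding genes with any pooled peak within 1000 bp of a start, with the same adjustment. The lists cover cholinergic neurons, sublateral neuron regulators, pharynx, body wall muscle, sex muscle and the M lineage, pan-neuronal genes, other neurotransmitter classes, axon guidance, neuropeptides, hypodermis and molting, collagens, intestine, germline, glia, homeobox genes, nuclear hormone receptors, ribosomal proteins, translation and proteostasis, mitochondrial respiration, histones and heat shock. Where several annotated genes share a symbol, each was counted, and counting 1 gene per symbol was an alternative chosen after the data were seen. The symbols efn-1 and daf-21 matched no annotated protein-coding gene.

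Overlap between replicates was counted among the 276 highest peaks of each replicate list, the number of optimal peaks, with 1 bp or more shared, and set beside 100 random placements of the same intervals on their chromosomes. Signal correlations run across peaks and have no p-value. The tests, the lists, the motif and the alternatives were fixed before the data were examined. The split of peaks by a tRNA, snoRNA, snRNA or rRNA gene within 250 bp of the summit was chosen after the highest peaks had been seen, and so was every comparison built on it. Genes were named by a rule fixed beforehand. It took the genes with a protein-coding start within 1000 bp of the summits of the 20 highest optimal peaks, ceh-24 and unc-119 whatever their values, up to 4 bound genes per list with the highest pooled signal, and the 5 highest optimal peaks without a protein-coding start in that window.

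The 6-mer test and the gene list test were tested on simulated data. In 20 sets of 276 background peaks with nothing added, 0 sets gave a called 6-mer among 2080. These sets had the GC content of the background, whereas the optimal windows were richer in G and C. Their outcome therefore does not measure how many 6-mers the main test calls through GC content alone. Of 12 6-mers planted in 10% of the windows, 9 were recovered, and of the same number planted in 5% of the windows, 1 was. With 222 random genes taken as bound, 1 of 50 runs called a list among the 9969 genes. These genes were drawn singly, whereas neighbouring genes can share 1 peak in the data, so the real rate of false calls may be higher. When 10% of the genes of a list were taken as bound, 3 of 12 lists with at least 20 genes were called, and at 20% all 12 were. Alternatives covered the ce10 lists, other overlap rules and numbers of peaks, a 500 bp promoter window, a 50 bp sequence window, the core word AAGTG, the 138 highest optimal peaks, top peaks of 1 replicate alone, and other backgrounds.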

Results

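CEH-24 is a homeodomain transcription factor of the NK-2 class in the nematode Caenorhabditis elegans. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in a transgenic strain, OP673, that expresses CEH-24 with GFP and FLAG fused to its C terminus in an unc-119 mutant background. Bound DNA was recovered with an antibody against GFP from whole late embryos of both sexes, 5 h after synchronization by bleaching. The group comprised 2 biological replicates and no second condition, so the measurements describe where the tagged factor was recovered and not a change. The relaxed list held 30000 peaks in replicate 1 and 28119 in replicate 2, and the pooled list held 30000. A deposited q-value of 0.05 or less was reached by 228 peaks of replicate 1, 729 of replicate 2 and 420 of the pooled list. All 276 optimal peaks reached it. Most entries of the relaxed and pooled lists are therefore not called binding sites, although each is termed a peak here. The depth behind the lists is unknown.

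The strongest CEH-24-GFP peaks lay at genes for small noncoding RNAs. The optimal list held 276 peaks, with pooled signal values from 102 to 556.5 and a median of 141. Of the 10 highest, 8 had a tRNA, snoRNA, snRNA or rRNA gene within 250 bp of the summit, and 11 of the 20 highest did. The highest peak (chromosome V, 8500343 to 8500744, summit 8500578) lay in an intron of a protein-coding gene, 1 bp from the snoRNA gene ZK994.7, with a signal value of 284 in replicate 1 and 271 in replicate 2. Small nucleolar RNAs guide chemical modification of ribosomal and other RNAs. The next peak (chromosome II, 11960637 to 11961009) was intergenic, 78 bp from the snoRNA gene W03C9.9, with values of 277 and 286. A peak on chromosome V (12303458 to 12303846) had its summit inside the intronic snoRNA gene C51F7.4, with values of 277 and 252. Another on that chromosome (15873805 to 15874174) was intergenic, 36 bp from T06C12.16, with 241 and 244, and a further one (11314049 to 11314372) was intronic, 44 bp from T03F7.8, with 220 and 191. None of these 5 peaks had a protein-coding start within 1000 bp.

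Across the optimal list, 148 of 276 peaks (53.6%, Wilson 95% interval 47.7 to 59.4) had a gene of these 4 kinds within 250 bp, against 397 of 29558 background peaks (1.34%). The odds ratio was 84.8 (95% interval 65.6 to 110, Fisher's exact p = 1.04e-186). Genes for tRNAs, which carry amino acids to the ribosome, accounted for 95 peaks (34.4% against 0.927% of background, odds ratio 56.1, 42.6 to 73.9). Genes for snoRNAs accounted for 46 (16.7% against 0.335%, odds ratio 59.7, 41.2 to 86.6) and genes annotated as snRNA for 7 (2.54% against 0.0913%), with 3 of the 6 bound snRNA genes encoding SL2 spliced leader RNAs. No optimal peak lay near 1 of the 20 annotated rRNA genes, of which 1 had any pooled peak. Counted by gene, 99 of 612 tRNA genes (16.2%, 13.5 to 19.3) and 43 of 346 snoRNA genes (12.4%, 9.36 to 16.3) had an optimal peak within 250 bp. No tRNA isotype stood apart from the others, with a lowest adjusted p of 0.969 over the isotypes tested. Most windows of tRNA peaks held some sequence repeated in the genome. Only 4 of 95 held solely 36-mers found once, against 45 of 46 snoRNA peaks. How much of each window was repeated was not measured.

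The share of peaks at these genes fell along the pooled ranking. Peaks with a tRNA gene made up 34.8% of ranks 1 to 138 (interval 27.3 to 43.04) and 34.1% of ranks 139 to 276 (26.7 to 42.3), then 11.7% of ranks 277 to 1000 (9.59 to 14.3) and 0.525% beyond rank 10000 (0.434 to 0.635). For snoRNA genes the share was 26.1% (19.5 to 33.99) in the upper 138 optimal peaks and 7.25% (3.98 to 12.8) in the lower 138. Summits near tRNA genes lay at a median of 24 bp downstream of the gene's 5′ end (quartiles -0.5 and 53). Those near snoRNA genes lay upstream in 36 of 46 cases, at a median of -39.5 bp.

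**Figure D1:**
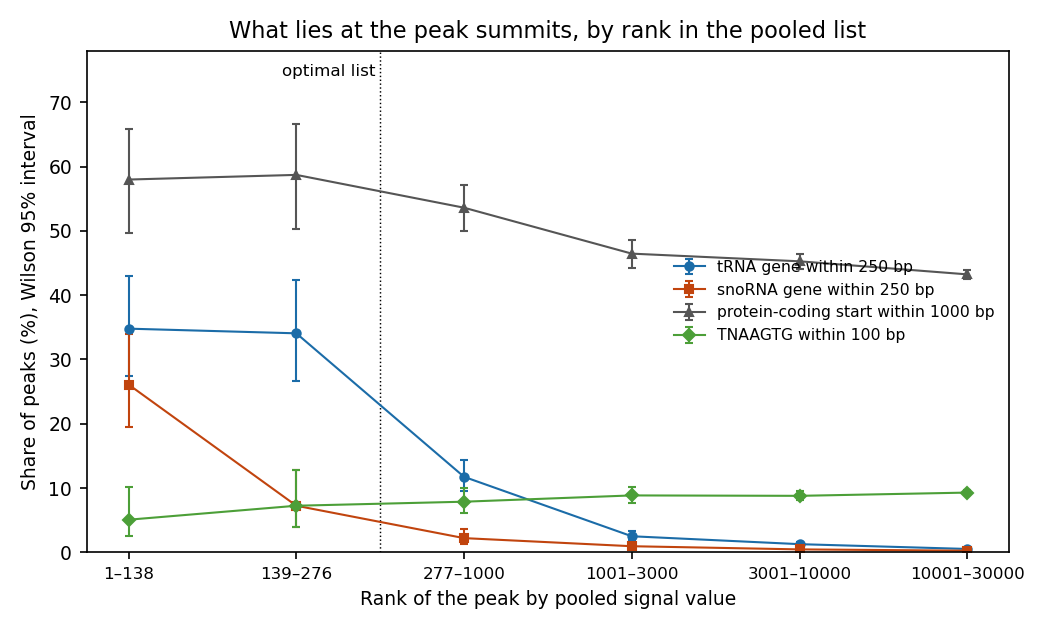
Share of pooled-list peaks (%, with Wilson 95% intervals) that have a tRNA or snoRNA gene within 250 bp, a protein-coding start within 1000 bp or the NK-2 class site within 100 bp of the summit, by rank of the pooled signal value. The tRNA share goes from 34.8% at ranks 1 to 138 to 0.525% beyond rank 10000, and the NK-2 class site from 5.07% to 9.29%.

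The replicates ranked many of the same regions first. Among the 276 highest peaks of each, 169 of replicate 1 (61.2%, 55.4 to 66.8) overlapped one of replicate 2, and random placement gave at most 5 in 100 trials. Both lists were derived with the same control, so their overlap is not that of independent experiments. The 276 of replicate 1 include 2 mitochondrial peaks, and with nuclear peaks only the count was also 169. With 552 peaks taken per replicate the share was 45.5%. All but 3 of the optimal peaks overlapped a peak of replicate 1, and all 276 overlapped a peak of replicate 2. Such overlap was largely fixed in advance, because the optimal peaks come from the same 2 replicates pooled and the relaxed lists are long. Only 171 of the optimal peaks (61.96%) ranked among the 276 highest in both. Across the 273 optimal peaks matched in both replicates, Spearman's rho of the signal values was 0.56 and Pearson's r of their log2 values was 0.65. These correlations describe peaks chosen by their pooled signal, so they have no reference value and do not measure how well the replicates agree. The 276 peaks form 262 separate regions, and some replicate peaks count for more than 1 optimal peak. No p-value is given. The optimal list was identical to the 276 pooled peaks with the highest signal value, with the next pooled peak at 102.04, so no single peak in it had to rank highly in each replicate.

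**Figure D2:**
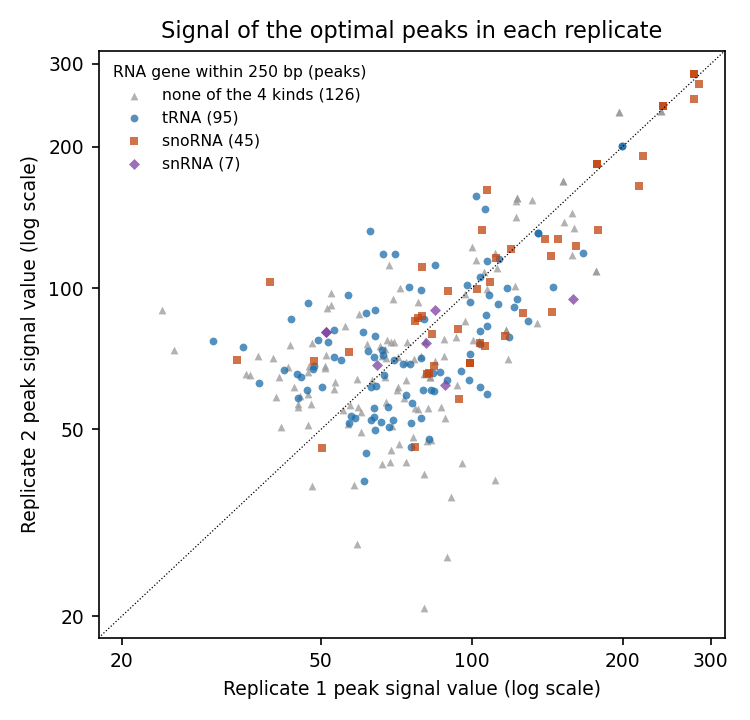
Signal value of the 273 optimal peaks that overlap a peak in each replicate, replicate 1 on the x axis and replicate 2 on the y axis (log scales, 1 point per peak, dotted line at equal values), by the kind of RNA gene within 250 bp of the summit. The snoRNA peaks reach the highest values in both replicates, up to 284 in replicate 1 and 286 in replicate 2.

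Optimal peaks were also found at promoters of protein-coding genes. A protein-coding start lay within 1000 bp of 161 of 276 summits (58.3%, 52.4 to 63.996), against 13034 of 29558 in the background (44.1%). The odds ratio was 1.77 (1.39 to 2.25, Fisher's exact p = 2.46e-06). The excess lay in the peaks away from the 4 RNA gene kinds. Of these 128 peaks, 106 (82.8%, 75.3 to 88.4) were at a promoter against 44.1% of like background peaks (odds ratio 6.001, 3.81 to 9.46). Of the 148 peaks near a gene of these kinds, 55 were (37.2%, odds ratio 0.75, 0.54 to 1.05). In the 106 promoter peaks the summit lay upstream of the nearest start in 91 cases (85.8%), against 52.4% of background promoter peaks (odds ratio 5.35, 3.12 to 9.18, Fisher's exact p = 5.47e-13), at a median of -179 bp. Of all 276 summits, 165 (59.8%) lay outside protein-coding genes and 92 (33.3%) in their introns. A further 9 lay in coding exons (3.26% against 15.2% of background), 6 in a 5′ UTR and 4 in a 3′ UTR.

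**Figure D3:**
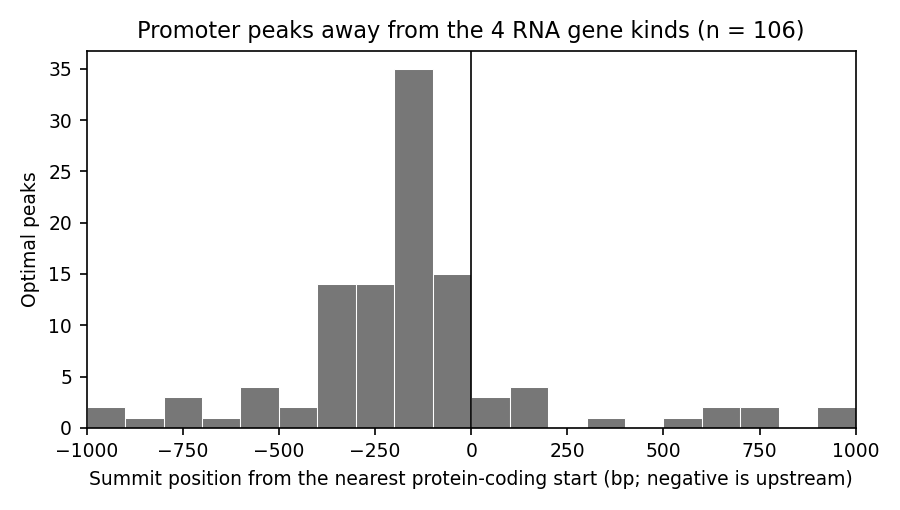
Number of optimal peaks by the summit's position relative to the nearest protein-coding start (bp, negative upstream, bins of 100 bp), for the 106 promoter peaks without a tRNA, snoRNA, snRNA or rRNA gene within 250 bp. The summits gather upstream of the start, at a median of -179 bp.

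Among the 20 highest peaks, those with a protein-coding start in the window included ftt-2 (WBGene00001502), which encodes a 14-3-3 protein. It had a pair of peaks, with summits at X 11605949 and X 11606151, 530 and 732 bp upstream of the start, with pooled signals of 437 and 303. The same replicate peaks underlay both, at 197 in replicate 1 and 237 in replicate 2. The summit 545 bp upstream of K12H4.5 (III 8043795 to 8044123) had a pooled signal of 475. The ribosomal protein gene rpl-3 (III 3867512 to 3867652, summit 270 bp upstream) had 287, with 132 in replicate 1 and 154 in replicate 2. A peak 38 bp upstream of idhg-1, for an isocitrate dehydrogenase subunit, and 629 bp upstream of mlcd-1 had 276. One between ears-2 and uncp-18, 21 and 71 bp upstream of their starts, had 288, and one upstream of spe-48 and Y51F10.11 had 295. The peak 191 bp upstream of T13C5.6 and 685 bp downstream of the start of C14F11.7 had 300.2. At sre-23, T02E1.2 and twk-5 the summit was also within 250 bp of a snoRNA gene (pooled signals 390.3, 360.3 and 308), and at C04A11.5 it was inside a leucine tRNA gene (398). The peak 906 bp downstream of the start of ints-8, for an Integrator complex subunit, had 312 and was intronic, and rpr-1, the gene for the RNA of RNase P, lay 15 bp from its summit.

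Among the 21 fixed gene lists, those of ribosomal protein and heat shock genes had an excess of bound promoters past the threshold, and each call was lost under some alternatives. An optimal peak lay within 1000 bp of a start of 222 of the 9969 background genes (2.23%). For ribosomal proteins it was 7 of 68 (10.3%, odds ratio 5.48, 2.54 to 11.8, Fisher's exact, Benjamini-Hochberg adjusted p = 0.00794). The highest were rpl-3, rpl-15 (pooled signal 179, summit 315 bp upstream), rpl-35 (176, 413 bp upstream) and rps-26 (148, 417 bp upstream, with a snoRNA gene nearby). The rps-26 summit was nearer the start of tmem-107, at 40 bp. The odds ratio stayed at a similar size with the top peaks of replicate 1 alone (6 of 65, 5.21, 2.29 to 11.8, Fisher's exact, adjusted p = 0.0490) and of replicate 2 alone (5 of 63, 4.40, 1.82 to 10.7, Fisher's exact, adjusted p = 0.223), where the call ended. It also ended among the 138 highest optimal peaks, with fewer bound genes (4 of 68, odds ratio 6.48, 2.44 to 17.2, Fisher's exact, adjusted p = 0.135). Over all alternatives the adjusted p of this list ranged from 0.000751 to 0.223.

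Heat shock genes had a peak in 4 of 17 cases (23.5%, odds ratio 14.9, 5.07 to 43.5, Fisher's exact, adjusted p = 0.00794), but 2 of the 4 are a pair of genes annotated with the symbol hsp-16.48, a small heat shock protein, that share 1 peak (pooled signal 103) lying between their 3′ ends. The others were hsp-1, a constitutive Hsp70 chaperone (125, 325 bp upstream), and hsp-60, the mitochondrial chaperonin (111, 627 bp upstream). The hsp-60 summit was nearer the start of Y22D7AL.10, at 186 bp. With 1 gene counted per symbol the list had 3 of 16 (odds ratio 11.5, 3.54 to 37.7, Fisher's exact, adjusted p = 0.0511). The call also ended with a 500 bp window (1 of 11, odds ratio 6.40, 1.15 to 35.7, Fisher's exact, adjusted p = 0.907) and among the 138 highest peaks (0 of 17, which allows up to 17.6%). With the top peaks of replicate 2 alone it was 2 of 15 (odds ratio 8.59, 2.21 to 33.4, Fisher's exact, adjusted p = 0.275) and with those of replicate 1 alone 1 of 16 (odds ratio 4.52, 0.842 to 24.3, adjusted p = 1). The translation and proteostasis list had 4 of 52 (Fisher's exact, adjusted p = 0.148), namely eif-3.C (159), eef-1G (113), hsp-1 and hsp-60, and no replicate 1 peak overlapped the one at eef-1G. The eef-1G summit was nearer the start of ctf-4 (24 bp) than that of eef-1G (204 bp). Mitochondrial respiration genes had 3 of 29 (Fisher's exact, adjusted p = 0.148), which were the cytochrome c oxidase subunit genes cox-6A (148, near an snRNA gene) and cox-5B (143) and the ATP synthase gene atp-1 (108). With the peaks near the 4 RNA gene kinds left out, a choice made after the data were seen, ribosomal proteins had 6 of 66 (Fisher's exact, adjusted p = 0.00674) and heat shock genes 4 of 15 (0.00160). Over all alternatives the adjusted p of the heat shock list ranged from 0.000975 to 1.

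No list of neuronal, muscle or other tissue genes passed the threshold, and many were too small for a call with 1 bound gene. No optimal peak was found at the start of any of 6 cholinergic neuron genes (which allows up to 50%), 5 sublateral neuron regulators (up to 60%), 12 pharynx genes (up to 25%), 33 body wall muscle genes (up to 9.09%), 35 axon guidance genes (up to 8.57%) or 56 homeobox genes (up to 5.36%). The same held for 4 genes of other neurotransmitter classes (up to 75%), 15 hypodermis and molting genes and 15 intestine genes (each up to 20%), 23 germline genes (up to 13.04%) and 6 glia genes (up to 50%). These limits lie above the 2.23% of all background genes, so a deficit was not detectable. The remaining lists had 1 or 2 bound genes and adjusted p-values of 0.922 or more. Of 11 sex muscle and M lineage genes, egl-17, which encodes a fibroblast growth factor that guides migrating sex myoblasts, was bound (X 489880 to 490013, pooled signal 208), with the summit inside a tRNA gene. The odds ratio of that list was 6.28 (1.13 to 34.9, Fisher's exact, adjusted p = 0.922) and rests on this 1 peak. Without the peaks near the 4 RNA gene kinds the list had 0 of 10 (up to 30%). Of 24 pan-neuronal genes, syd-2, for the synaptic scaffold liprin-alpha, had a peak 371 bp upstream (104.1). Of 62 neuropeptide genes, flp-23 had one (107) near a tRNA gene, as did 2 of 62 collagen genes, col-85 (259) and col-185 (150.4). Of 128 nuclear hormone receptor genes, nhr-255 (178, near a tRNA gene) and nhr-142 (109.8) were bound, and of 33 histone genes his-72 (109), for a replacement histone H3, near a snoRNA gene. The nhr-142 summit was nearer the start of F44E7.9 (170 bp) than that of nhr-142 (507 bp).

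The NK-2 class site TNAAGTG was not more frequent at optimal peaks than in the background. It was found in 17 of 276 windows (6.16%, 3.88 to 9.64) against 2697 of 29558 (9.12%), an odds ratio of 0.67 (0.41 to 1.09, Fisher's exact p = 0.0924). With the shorter core AAGTG the direction turned, with 41.7% against 35.97% (odds ratio 1.27, 1.00 to 1.62, Fisher's exact p = 0.0510). Of the 8 6-mers that contain the core, CAAGTG (13.04% against 7.61%, Fisher's exact, adjusted p = 0.00942) and AAGTGT (17.8% against 11.8%, adjusted p = 0.0157) were more frequent at optimal peaks. Against matched background AAGTGT kept an adjusted p of 0.0112 and CAAGTG had 0.0797. In the 128 peaks away from the 4 RNA gene kinds, TNAAGTG was present in 5.47% against 9.84% of the matched background (Fisher's exact p = 0.115), and the core in 49.2% against 37.8% (odds ratio 1.59, 1.11 to 2.29, p = 0.0133).

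Of the 2080 6-mers, 439 were more and 202 less frequent in optimal peaks than in the background at an adjusted p below 0.05. The highest were CGAACC (30.1% against 3.68%, Fisher's exact, adjusted p = 1.80e-46) and GTTCGA (35.9% against 6.60%, adjusted p = 4.44e-42). These words are part of the B box (GWTCRANNC), the internal promoter element of tRNA genes that RNA polymerase III transcription factors bind. A B box was present in 88 of 95 tRNA peaks (92.6%), 25 of 46 snoRNA peaks (54.3%) and 9 of the 128 peaks away from the 4 RNA gene kinds (7.03%), against 6.89% of the background. Because tRNA genes hold this element, its share in tRNA peaks largely follows from how these peaks were defined. Optimal windows were richer in G and C than the background (mean 44.2% against 35.8%), and against the matched background 131 6-mers were more and 62 less frequent, with the same pair of words leading. Without the peaks near the 4 RNA gene kinds and against matched background, 31 were more and 3 less frequent. These were led by CGCACA (29.7% against 7.58%, Fisher's exact, adjusted p = 1.41e-08) and GCGCGC (21.1% against 4.53%, adjusted p = 7.80e-07), and among them was AAGTGT, which contains the core (25.8% against 10.5%, adjusted p = 0.000718).

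Neither gene carried by the transgene had an optimal peak within 15 kb. At ceh-24 itself (WBGene00000447, V 13813231 to 13815350) the highest pooled peak within 1 kb of the gene had a signal of 52.3 and rank 3419 (summit 13812359). In the replicates' own lists the highest peak in that range had 36.2 in replicate 1 (summit 13812370) and 28.6 in replicate 2, at a different summit (13812635). At unc-119 (WBGene00006843, III 10902641 to 10908935), the rescue marker, it had 33.8 and rank 16105.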

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

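The highest signal in the replicate 1 list was on the mitochondrial genome, and the 276 highest peaks of replicate 1 used for the overlap of the replicates include 2 such peaks. That list holds 3 mitochondrial peaks. The highest (12122 to 12591) has a signal value of 538, above the highest nuclear value of 284 in that replicate, and the next (10836 to 11305) has 230 and rank 7. Without mitochondrial peaks the overlap was also 169 of 276. The lists of replicate 2 and of both replicates pooled hold 0 mitochondrial peaks. The cause was not tested.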

How the results depend on the processing

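Alternatives that leave out the peaks near a tRNA, snoRNA, snRNA or rRNA gene (4 RNA gene kinds), leave out mitochondrial peaks or count 1 gene per symbol, and all alternatives for the share of peaks near the 4 kinds, were chosen after the data were seen. Of the values recomputed under an alternative, 52 stayed the same, 10 moved, 7 weakened, 1 strengthened and 1 reversed. For tests, the same meant an unchanged direction and side of the threshold. For the share of top peaks in common and for rho, it meant a value within the main interval. For counts it meant a value within a fixed ratio of the main count, with no measure of spread. The share near the 4 kinds stayed past its threshold under each alternative, from 22.1% with the summit inside the gene to 63.8% of the 138 highest optimal peaks, and so did the promoter share, from 41.7% with a 500 bp window to 82.8% without the peaks near the 4 kinds. The core AAGTG reversed the direction of the NK-2 class site (41.7% against 35.97%). The ce10 list held 262 optimal peaks, and the stricter list 138 by construction. The share of top peaks in common fell to 51.8% with summits within 100 bp and to 45.5% with 552 peaks. The enriched 6-mers numbered 131 against the matched background and 113 without the peaks near the 4 kinds. The gene lists past the threshold, 2 with each gene counted, numbered 1 with a 500 bp window, 1 with 1 gene per symbol and 0 among the 138 highest optimal peaks, where fewer genes were bound.

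With the top peaks of 1 replicate alone, the promoter share ranged from 56.9% to 57.6%, the NK-2 class site from 5.43% to 6.16% (Fisher's exact p = 0.0346 without replicate 2, where the site was less frequent than in the background), the share near the 4 kinds from 48.2% to 50.7%, the enriched 6-mers from 370 to 480 and the lists from 0 to 1. The cause of these differences was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits could not be measured.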

Other observations

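The items and tests in this part were chosen after the results were seen, except those of the NK-2 class site at promoters and of the transgene. Some RNA genes outside the 4 kinds had an optimal peak within 250 bp and others did not. Whatever other gene lay nearby, 113 of 276 optimal peaks (40.9%) had a gene annotated as ncRNA within 250 bp, against 6.002% of background, 3 (1.09% against 0.196%) a microRNA gene, 1 (0.362% against 0.474%) a lincRNA gene and 2 (0.725% against 3.42%) a piRNA gene. The gene rpr-1 for the RNA of RNase P, which trims tRNA precursors, lies 15 bp from the summit of the peak ranked 11 (I 13463692 to 13464187, pooled signal 312), the one assigned to ints-8 by its coding start. The gene mrpr-1 for the RNA of the related RNase MRP had a peak of rank 72 (183). Of the 5 srpr genes, which encode the RNA of the signal recognition particle, 3 had an optimal peak, srpr-2.2 (225), srpr-1.1 (130) and srpr-1.2 (111), while srpr-2.1 (96.995, rank 315) and srpr-3 (70.2, rank 892) lay below the threshold. Of the other ncRNA genes with a gene symbol, yrn-1, lfor-1 and lfor-2 had no pooled peak within 250 bp, and linc-171 (55.97, rank 2479), rncs-1 (60.2, rank 1738), tts-1 (67.9, rank 1034) and tts-2 (54.3, rank 2884) were below the threshold. The microRNA genes were mir-51 (272), mir-52 (225) and mir-58a (122).

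Chromosome X held 64 of the 276 optimal peaks (23.2%, against 16.8% of pooled peaks). It also holds 276 of the 612 nuclear tRNA genes, and 55 of these (19.9%, 15.6 to 25.04) had an optimal peak against 44 of 336 on the autosomes (13.1%, 9.90 to 17.1), with an odds ratio of 1.65 (1.07 to 2.54, Fisher's exact p = 0.0271, 1 comparison with no adjustment). This is not particular to X. Chromosome III had an optimal peak at 14 of 64 tRNA genes (21.9%, 13.5 to 33.4), and it held 4.14 optimal peaks per Mb against 3.61 on X.

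The excess of peaks at genes of the 4 kinds was weighed against 3 explanations. GC content is argued against as the sole cause, since against a background matched on it the odds ratio was 38.5 (27.8 to 53.2). It was 84.8 against the whole background, so part of the excess may go with GC content. Reads shared between near-identical copies are argued against for the snoRNA genes, where 45 of 46 peaks had a unique window. The snoRNA and snRNA peaks with such a window kept an odds ratio of 86.7 (50.01 to 150.3). Of these 47 peaks, 45 were snoRNA peaks, so the value does not settle the question for snRNA genes. For tRNA genes the question of shared reads also stays open, because only 4 of 95 peaks had such a window (odds ratio 8.45, 2.90 to 24.6). Recovery of these loci without binding by CEH-24 itself may also contribute and cannot be told apart from binding, because no ChIP from untagged worms was analysed here and the NK-2 class site at these peaks (odds ratio 0.675, 0.353 to 1.29 against matched background) decides neither way.

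The promoter excess may reflect commonly bound or open promoters rather than the NK-2 class site. At promoter peaks TNAAGTG was found in 5.59% against 9.44% of matched promoter background (Fisher's exact p = 0.114). The hypothesis predicted no excess of the site. The comparison measured neither openness nor binding by other factors, so it cannot tell this hypothesis from other reasons for no excess. The core AAGTG was more frequent there (45.96% against 36.6%, odds ratio 1.48, 1.07 to 2.04, Fisher's exact p = 0.0211). The comparison set beforehand used TNAAGTG only. The core is a shorter word that need not be part of an NK-2 class site, so its excess does not decide the question. The data leave the hypothesis open.

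Extra copies of the transgene could raise the number of peaks around ceh-24 and unc-119. Within 15 kb there were 15 pooled peaks at ceh-24 (exact Poisson interval 8.40 to 24.7) against a median of 7 in 1000 random windows of the chromosome, and 11 at unc-119 (5.49 to 19.7) against a median of 10. These are the 91.9th and 52.5th percentile, below the 95th that had been set as the bound (16 and 18 peaks). That outcome had been set beforehand as the one without such an effect. The intervals were not part of that rule, but both reach past the bound, so the question stays open. A further hypothesis was that unannotated genes with a B box lie under the other 128 optimal peaks. A B box was about as frequent there as in matched background (odds ratio 1.058, 0.53 to 2.12), an interval too wide to exclude a small excess.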
